A study of Rattus norvegicus with 6 samples.

How the data were processed

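RNA from 6 samples of 1 rat keratinocyte line was measured on 1 Affymetrix rat 230 2.0 array each, 3 unirradiated and 3 irradiated; groups were taken from the source descriptions of the samples. RNA was extracted with Trizol and polyA RNA was labelled with biotin, per the labels' protocols. The data were processed with BRB ArrayTools 3.3.0, per the submitters' design text. The software that made the probe set values, its summary method and its scaling target are not given in the sources used here. The values deposited by the authors are probe set intensities on a linear scale, with 1 decimal. In the deposited table, the mean left after trimming 2% of the probe sets at each end was 150.05 on 5 arrays and 150.04 on irradiated replicate 2, so that each array had been scaled to a common level. Other quantiles differed between arrays, so the values had not been quantile normalized; other steps are not given in the sources used here. By a rule fixed beforehand (trimmed means within 10% of each other), the table counted as normalized and was kept as deposited.

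Of 31099 probe sets, 57 control probe sets were left out. Probe sets below the 40th percentile of mean intensity over all 6 arrays were also left out, which kept 18625. The values were taken as log2(intensity + 16), a scale that understates the change of dim genes, and all fold changes on the log2 scale are on it; folds given as N-fold are ratios of mean intensities. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), irradiated minus unirradiated, two-sided, with no covariate. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. Single values were compared by an exact permutation test, for which 3 against 3 arrays cannot give a p under 0.1. The number of arrays limits the precision: the median SE of a log2 change was 0.14.

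Gene names came from the platform's annotation table. Of the probe sets other than controls, 20826 had 1 gene symbol, 436 had several and 9780 had none there; symbols were compared by Entrez ID with a RefSeq table of rat assembly GRCr8, and 0 differed. Of the changed probe sets, 54 had no single symbol and are not named here. A gene was represented by its tested probe set with the highest mean; 19 genes not called by it had another probe set past the threshold. No genome coordinates were used.

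The test, the lists, the rule for named genes and all alternatives except 1 were chosen before the data were examined. The 20 gene lists covered pathways and cell markers, among them markers of other skin cell types; no gene was in 2 lists, and 137 listed genes were not named under 1 symbol. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists; 10 passed. With an estimated correlation 1 passed. By fry 5 passed for a common direction and 16 for change in either direction. Named genes were the 10 largest rises and 10 largest falls among called genes without overlap between groups, the 4 members of each list with the smallest p, and Cdkn1a, Mdm2, Ccng1, Ccnb1 and Cdk1.

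The procedure was tested on simulated data with 18625 probe sets, 200 of them changed. It recovered 46% of changes of 0.5 and 98% of changes of 1 on the log2 scale; 6.49% of calls were false and 0 had the wrong direction. With no change simulated, 0 of 20 lists passed, and a simulated shift of 0.3 in G2 and mitosis genes called that list and 0 others. The simulated noise was independent between genes, so this check cannot show how the list test behaves where genes vary together. In the real data the estimated correlation reached 0.42, for ribosomal protein genes. Alternatives were pseudocounts of 1 and 64, a floor of 10, quantile normalization, median centring, no filter and a filter at the 60th percentile, eBayes without trend and robust, an unadjusted threshold of 0.001, counting genes, averaging a gene's probe sets, the other list tests and leaving out each array. Gene lists of the same size were also drawn 10000 times among genes of matching mean intensity. Cyclic loess normalization was added after seeing the data.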

Results

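Gene expression was measured in an immortalized line of rat keratinocytes, the main cell type of the epidermis, which came from back skin of newborn Sprague-Dawley rats. Each of 6 samples was hybridised to 1 Affymetrix rat 230 2.0 array, on which a gene is read by 1 or more probe sets. The 3 unirradiated samples had no treatment. The 3 irradiated samples received 3 Gy of 56Fe ions, heavy charged particles of the kind found in space radiation, at 1.01 GeV per nucleon. The time between irradiation and RNA extraction is not given in the labels used here. By its title, the series asked how the ions affect gene expression and arrest of the cell cycle. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say whether the arrays of both groups were hybridised and scanned together, and a difference in processing between the groups was not tested. Correlations of log2 values between arrays were 0.985 to 0.988 within groups and 0.983 to 0.987 between groups.

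After irradiation, the keratinocytes held more mRNA of the genes that carry cells through G2 and mitosis, while mRNA of the classical p53 targets Cdkn1a, Mdm2 and Ccng1 gave no detectable difference. The mitotic kinesin Kif20a rose 2.33-fold, from an intensity of 357 ± 19.6 to 833 ± 51.6 (mean ± SD, n = 3). Cdc25b, a phosphatase that activates cyclin-dependent kinases at entry into mitosis, rose 2.25-fold, from 682 ± 66.8 to 1536 ± 72.2. The uracil-DNA glycosylase gene Ung, of base excision repair, fell 2.35-fold, from 218 ± 10.5 to 92.8 ± 8.32. Limma called 383 of 18625 tested probe sets changed at an adjusted p under 0.05, 279 higher and 104 lower.

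Counted with 1 probe set per gene, 206 genes were higher and 77 were lower out of 10345 tested. All 383 changed probe sets had 3 irradiated values on one side of the 3 unirradiated ones, as did 19.2% of all tested probe sets, where chance gives 10%. Most changes were moderate, with a median size of 0.64 on the log2 scale, and 32 changed probe sets exceeded 2-fold on that scale. This count is not by ratios of mean intensities, and it leaves out some called genes over 2-fold by that ratio. Cenpf, for example, rose 2.05-fold by the ratio of means, with a log2 change of 0.97. At an unadjusted p under 0.05 there were 2482 probe sets, against 931 expected by chance. Of 77 additional tested probe sets of the changed genes, 73 moved in the direction of the call and 0 passed the threshold in the opposite direction, while 27 passed it in the same direction. The number of calls was lower in every fit without 1 array (202 to 279), where fewer arrays give less power. A call lost in such a fit, here and below, need not mean that it rests on that array. The number of calls moved by over 1.5 times without irradiated replicate 2 (202), irradiated replicate 1 (228) or unirradiated replicate 1 (232). It was 171 when the variance was modelled without an intensity trend and 223 without a filter on low values. Of 45 genes named here that changed, 26 kept their call without the trend, Cdca2, Tp63, Myc, Mt2A, Gadd45a and Cdk1 being among those that lost it, and 33 kept it without the filter.

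Among called genes with a single symbol, the largest rise on the log2(intensity + 16) scale was in Hjurp. This chaperone of the centromeric histone CENP-A rose 2.62-fold, from 176 ± 30.7 to 462 ± 44.0, with a log2 change of 1.32 ± 0.13 (SE; limma adjusted p = 1.9e-04). It was followed by Cdca2 (1.24), Kif20a (1.19), Troap (1.18), Ccnf (1.17), Cdc25b (1.16), Dpysl5 (1.15), Psrc1 (1.05), the mitotic kinase Plk1 (1.04) and the spindle protein Fam83d (1.03), all as log2 changes. Dpysl5 was dim, at 6.97 ± 5.92 and 35.0 ± 12.5. Its unirradiated mean lies under the floor of 10, so the ratio of means (5.03-fold) is not a reliable size. With values under 10 set to 10, the log2 change of Dpysl5 was 1.58 against 1.40 for Hjurp. With a pseudocount of 64, the log2 changes of the dim genes Dpysl5, Psd and Cox6a2 were 0.48, -0.60 and -0.43. Among the same genes, the largest falls on the log2 scale were in Psd (-1.12), Ung (-1.10), Noa1 (-0.83), the histone gene H2ac25 (-0.82), Hoxa3l1 (-0.77), Qtrt1 (-0.75), Calml5 (-0.74), Cox6a2 (-0.74), the chemokine gene Ccl20 (-0.74) and Wdr46 (-0.74). Over all called probe sets, those without a single symbol included, the largest changes were 1.34 and -1.29. A dimmer probe set of Qtrt1 had a log2 change of 0.09 and did not pass. Leaving out 1 array ended the calls of 5 of these 20 genes by limma. Dpysl5 lost its call without unirradiated replicate 2 or 3 (adjusted p up to 0.0906), kept it without unirradiated replicate 1, and fell below the intensity filter, so was not tested, without any 1 of the irradiated arrays. The call ended for Hoxa3l1 without unirradiated replicate 1 or 3 or irradiated replicate 1 (up to 0.0601), and for Psd without any array but irradiated replicate 3 (up to 0.138). The call of Qtrt1 ended without any array but unirradiated replicate 1 (up to 0.139), and that of Cox6a2 without any of the 6 (up to 0.179).

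**Figure D1:**
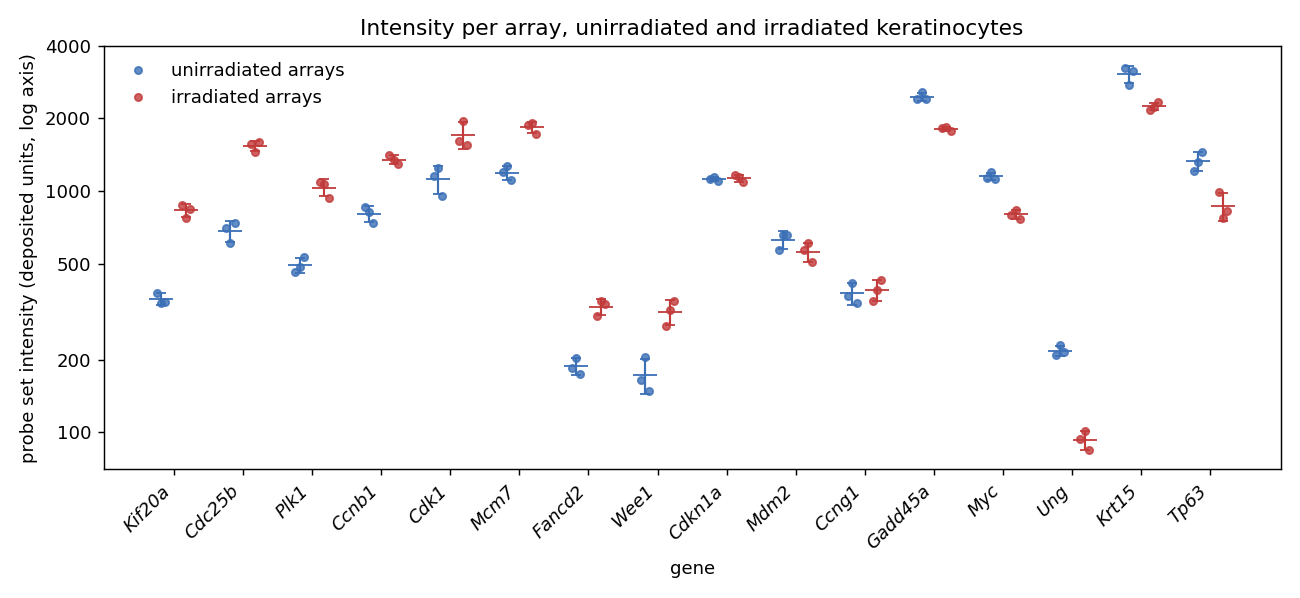
Probe set intensity (deposited units, log axis) of 16 named genes on each array; points are arrays, the wide bars are group means and the whiskers are SD (n = 3). Kif20a lies at 357 and 833 in the unirradiated and irradiated means, and Cdkn1a at 1121 and 1129.

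Genes of G2 and mitosis rose together. Of 69 measured members of this list, 53 rose, 0 fell and 16 did not pass, and adjusted over the list alone 62 rose. All 69 log2 changes were above 0, with a median of 0.69. The mean of the list was 0.63, 0.65 and 0.67 above the unirradiated mean in the 3 irradiated arrays. Nusap1, which bundles spindle microtubules, rose from 1522 ± 32.0 to 2753 ± 12.8, and Plk1 rose from 493 ± 34.2 to 1034 ± 85.1. Cyclin B1 (Ccnb1) rose by a log2 change of 0.73 ± 0.08 and its kinase Cdk1 by 0.61 ± 0.11, both SE, with limma adjusted p = 4.1e-04 and 0.0121. Without irradiated replicate 2, the change of Cdk1 was 0.51 and its adjusted p was 0.0553. Camera with a preset correlation gave the list an adjusted p = 3.6e-70, and it was the only 1 of 20 lists to pass with an estimated correlation (adjusted p = 0.0051).

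DNA replication genes and genes of DNA damage signalling and repair also held many members that rose. Of 61 measured replication genes, 13 rose, 0 fell and 48 did not pass, and adjusted over the list alone 37 rose. Mcm7, a subunit of the replicative helicase, rose from 1194 ± 81.8 to 1838 ± 93.8. Pold1, the catalytic subunit of DNA polymerase delta, rose by a log2 change of 0.70, the histone chaperone gene Asf1b by 0.65 and the clamp loader gene Rfc4 by 0.43. The call of Rfc4 ended in limma without unirradiated replicate 2 or 3 or irradiated replicate 2 or 3 (adjusted p up to 0.0626). The median log2 change of the replication list was 0.33 (camera adjusted p = 2.3e-22, and adjusted p = 0.0842 with an estimated correlation).

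Of 66 measured genes of DNA damage signalling and repair, 12 rose, 2 fell and 52 did not pass, and adjusted over the list alone 22 rose and 3 fell. Fancd2, of the Fanconi anaemia pathway, rose from 188 ± 14.9 to 331 ± 25.4, and the checkpoint gene Topbp1 rose from 142 ± 26.0 to 279 ± 18.5. The log2 change of Topbp1 was 0.91, while a dimmer probe set of it had a change of 0.44 and did not pass. The 2 members that fell were Ung and Apex1, which act one after the other in base excision repair. Apex1 fell by 0.62 on the log2 scale, while a dimmer probe set of it had a change of 0.40 and did not pass. The median of the list was 0.18 (camera adjusted p = 5.8e-08, and adjusted p = 0.146 with an estimated correlation).

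Among 37 measured cell cycle regulators, changes went both ways: 4 rose, 2 fell and 31 did not pass, and adjusted over the list alone 7 rose and 2 fell. Wee1 and Pkmyt1, kinases that hold Cdk1 inactive before mitosis, rose by log2 changes of 0.82 and 0.84, and Fzr1, an activator of the anaphase-promoting complex, rose by 0.82. The Wee1 value came from a probe set that may detect related transcripts, and a second probe set of the gene had a change of 0.33 and did not pass. The growth regulator Myc fell by 0.51 on the log2 scale, from 1150 ± 40.4 to 800 ± 33.0. The other members that changed, named after their values were seen, were the cyclin-dependent kinase inhibitor gene Cdkn2c (0.49) and Sfn (-0.45), which encodes 14-3-3 sigma. The median of the list was 0.08 (camera adjusted p = 0.0387, and adjusted p = 0.175 with an estimated correlation). The call of the list ended without unirradiated replicate 2 (median 0.07), unirradiated replicate 3 (0.07) or irradiated replicate 3 (0.08), with camera adjusted p up to 0.0769. With median centring the median was 0.05.

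The p53 target genes showed no common direction (fry adjusted p = 0.628). Of 40 measured, 2 rose, 2 fell and 36 did not pass, and adjusted over the list alone 2 rose and 4 fell. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was at 1121 ± 24.2 without and 1129 ± 39.6 with irradiation, a log2 change of 0.01 with a 95% confidence interval from -0.15 to 0.17. The sign of this small change turned with median centring (-0.02). The log2 change was -0.16 in Mdm2 (-0.37 to 0.04; -0.09 without irradiated replicate 3) and 0.05 in Ccng1 (-0.18 to 0.27). The 2 members that rose were Psrc1 (1.05) and Gtse1 (0.68), known also for roles at the spindle and in G2. Gadd45a fell by 0.44 and Ddit4 by 0.39 on the log2 scale. The call of Ddit4 ended in limma without unirradiated replicate 1 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.0752). The list had a median of 0.02 and a mean of 0.02, while camera placed it lower than other genes (adjusted p = 0.686, and adjusted p = 0.675 with an estimated correlation). The fry test for change in either direction gave an adjusted p = 2.4e-06, the smallest of the 20 lists, next to 5.0e-06 for G2 and mitosis genes. Passing that test is not particular to p53 targets, since 16 of the 20 lists passed it.

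**Figure D2:**
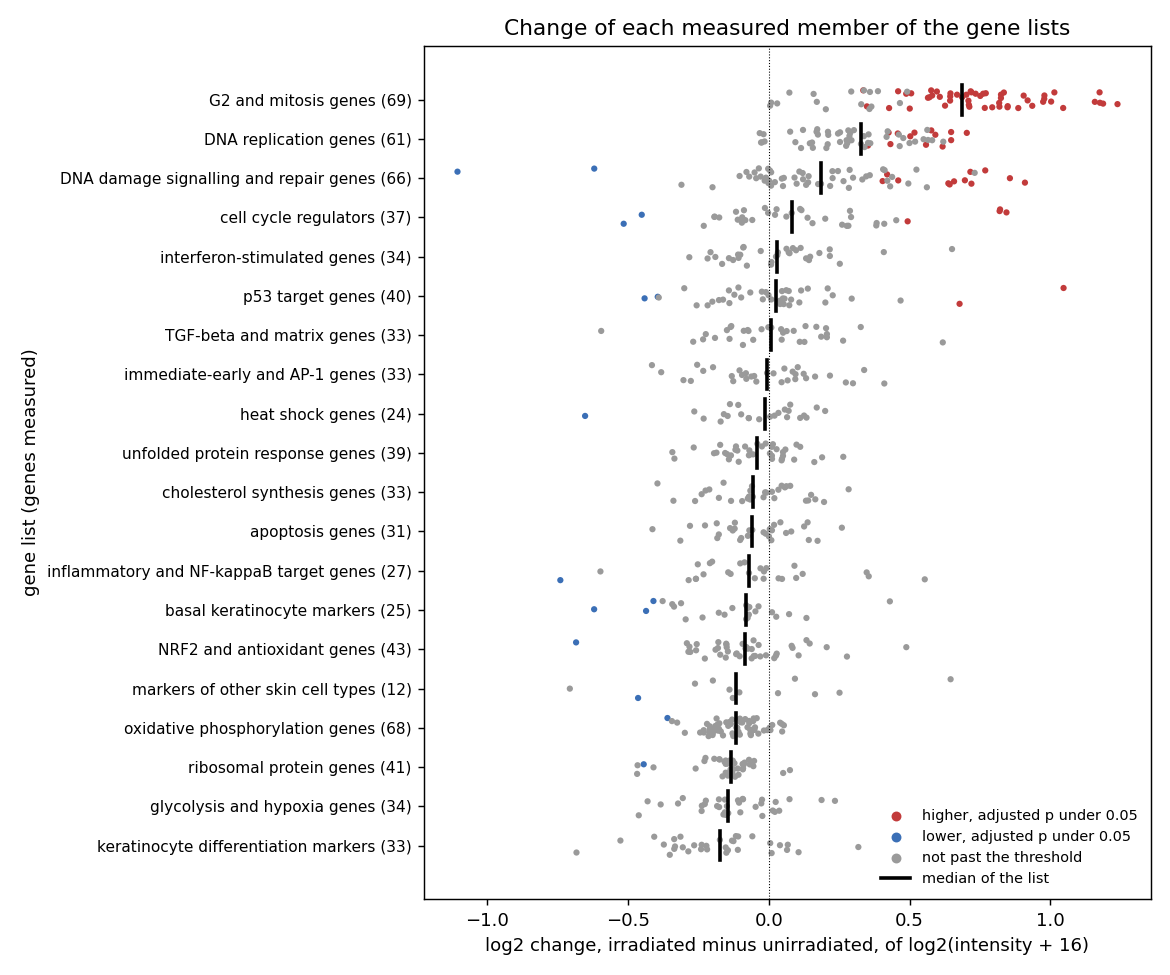
Log2 change (irradiated minus unirradiated, of log2(intensity + 16)) of each measured member of the 20 lists; each point is a gene, red for higher and blue for lower at an adjusted p under 0.05, grey otherwise, and black bars are list medians. The median of G2 and mitosis genes lies at 0.69 and that of p53 target genes at 0.02.

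Several keratinocyte markers were lower. Tp63, the transcription factor of basal keratinocytes, fell from 1332 ± 122 to 864 ± 115, and the basal keratins Krt15 and Krt17 fell by 0.44 and 0.41 on the log2 scale. These were the 3 of 25 measured basal markers that fell, while 0 rose and 22 did not pass, and adjusted over the list alone 6 fell. Krt14 had a log2 change of -0.38 with a limma adjusted p = 0.0502, and of -0.24 with quantile normalization. It passed narrowly with a floor of 10 (limma adjusted p = 0.0468), median centring (0.0482) and robust eBayes (0.0428). In 13 other settings Krt14 did not pass. A second probe set of Tp63 had a change of -0.46 and did not pass. The call of Krt15 ended without unirradiated replicate 1 or 3 or irradiated replicate 1 (limma adjusted p up to 0.0758). That of Krt17 ended without any array but irradiated replicate 2 (up to 0.105), and with quantile normalization (adjusted p = 0.198). The basal list had a median of -0.08 and a mean of -0.15 (camera adjusted p = 8.0e-05, and adjusted p = 0.355 with an estimated correlation). That median was -0.12, -0.18 and -0.05 without unirradiated replicate 1, 2 and 3, -0.17 without irradiated replicate 3, -0.13 with a gene's probe sets averaged and -0.05 with cyclic loess normalization, a setting chosen after seeing the data. Brightness moved the same way: lists of genes drawn to match the basal markers in intensity had a median of -0.05, and 16.4% of 10000 draws lay as low as the list.

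Of 33 differentiation markers, 0 passed limma's threshold in either direction, also adjusted over the list alone. Their values were mostly below 0: 26 of 33, with a median of -0.17. Tgm3 had a log2 change of -0.68, Serpinb2 of -0.41, Klf4 of -0.31 and Cst6 of -0.26. The dim gene Tgm3 was at -1.24 with a pseudocount of 1, -0.30 with 64 and -0.38 without irradiated replicate 3, and Serpinb2 was at -0.25 without irradiated replicate 1. Camera gave the list an adjusted p = 8.0e-05, and adjusted p = 0.169 with an estimated correlation. Calml5, which encodes a calmodulin-like skin protein and is 1 of the 10 largest falls, went from 694 ± 21.3 to 409 ± 26.9. Of 12 measured markers of other skin cell types, 0 rose and 1 fell, the fibroblast collagen gene Col3a1 (-0.46), while adjusted over the list alone 1 rose and 2 fell. The call of Col3a1 ended without any array but unirradiated replicate 2 (limma adjusted p up to 0.15). The median of that list was -0.12 (camera adjusted p = 0.342), and it turned to 0.055 without unirradiated replicate 3.

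Genes of translation and energy metabolism had slightly lower values as groups, with few single calls. Of 41 ribosomal protein genes 39 had a log2 change below 0, with a median of -0.13, and 1 fell, Rpl21 (-0.44). Of 68 oxidative phosphorylation genes 61 were below 0, with a median of -0.12, and 1 fell, Uqcrh (-0.36). Of 34 glycolysis and hypoxia genes 27 were below 0, with a median of -0.15, and 0 passed limma. In these 3 lists 0 members rose, and the counts adjusted over the list alone were the same. Camera gave adjusted p = 2.7e-08, 7.5e-09 and 0.0017, and adjusted p = 0.355, 0.243 and 0.434 with an estimated correlation, in that order. The brightest probe sets moved in the same direction. The tenth of probe sets with the highest mean intensity had a median log2 change of -0.07, and the 99th percentile of intensity was 2731 ± 46.8 without and 2561 ± 112 with irradiation (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). With quantile normalization the median was -0.0053 for the ribosomal list (camera adjusted p = 0.653) and -0.06 for oxidative phosphorylation (camera adjusted p = 0.0059). In gene lists drawn to match them in intensity, the median was -0.12 and -0.07. The mean of the ribosomal list was -0.26 in irradiated replicate 2, against -0.09 and -0.11 in the other irradiated arrays, and without that replicate the median of the list was -0.06. The call of the glycolysis list ended without unirradiated replicate 3 (median -0.09, camera adjusted p = 0.124). That of Rpl21 ended without any unirradiated array or irradiated replicate 3 (limma adjusted p up to 0.119) and with quantile normalization (0.147), and that of Uqcrh without unirradiated replicate 1 or 2 or irradiated replicate 2 or 3 (up to 0.131).

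Few stress and immune genes passed the test. Of 43 NRF2 and antioxidant genes, 0 rose and 1 fell, the metallothionein gene Mt2A, from 4100 ± 465 to 2547 ± 280, and adjusted over the list alone 1 rose and 3 fell. The median of this list was -0.08 (camera adjusted p = 0.0017, and adjusted p = 0.104 with an estimated correlation), and -0.05 with cyclic loess normalization. Lists drawn to match it in intensity had a median of -0.045, and 6.69% of 10000 draws lay as low. Of 27 inflammatory and NF-kappaB target genes, 0 rose and 1 fell, Ccl20, from 847 ± 84.0 to 506 ± 108, and adjusted over the list alone 2 rose and 3 fell. Of 24 heat shock genes, 0 rose and 1 fell, Hspa4 (-0.65), also adjusted over the list alone. Limma called 0 of 31 apoptosis genes, 34 interferon-stimulated genes, 33 immediate-early and AP-1 genes, 33 TGF-beta and matrix genes, 33 cholesterol synthesis genes and 39 unfolded protein response genes. Adjusted over the list alone, 1 interferon-stimulated gene rose, 2 unfolded protein response genes fell and 0 members of the other 4 lists passed. Camera called none of these 6 lists, nor the inflammatory or heat shock list, with adjusted p = 0.110, 0.976, 0.524, 0.927, 0.195, 0.110, 0.15 and 0.161 in that order. Xiap, of the apoptosis list, had a log2 change of -0.41, Usp18, induced by interferon, of 0.65 (0.39 with a pseudocount of 64) and the chaperone gene Hspa5 of -0.33.

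**Figure D3:**
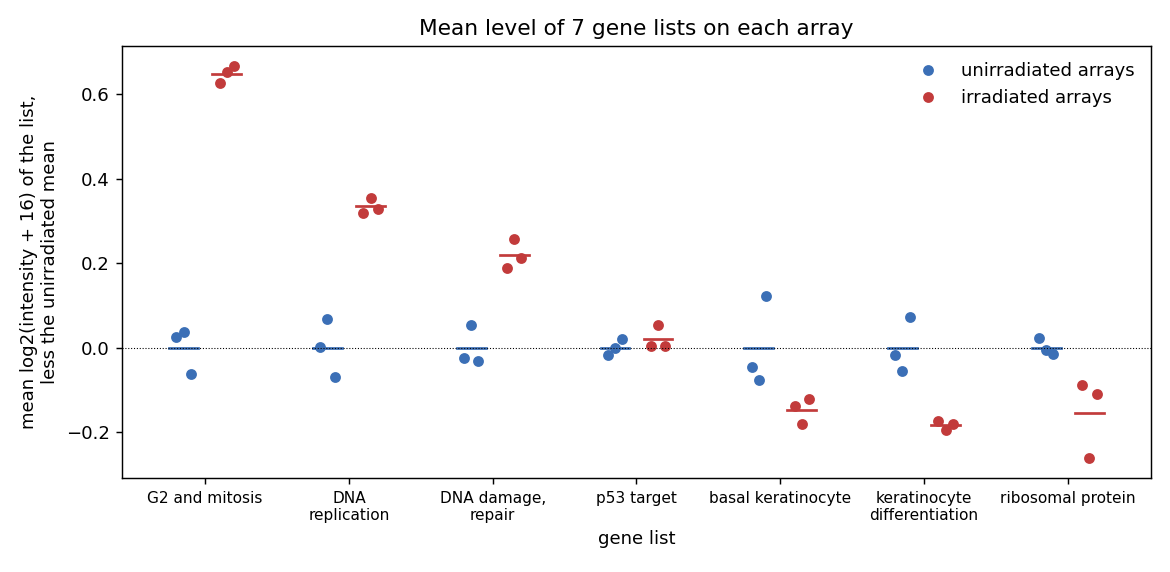
Mean log2(intensity + 16) of 7 gene lists on each array, less the unirradiated mean; points are arrays and bars are group means (n = 3). The irradiated arrays lie at 0.63 to 0.67 for G2 and mitosis genes and between 0.00331 and 0.0528 for p53 target genes.

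Measures of array and RNA quality were also compared between the groups. By exact permutation tests, two-sided, the ratio of 3' to 5' control signal, a measure of RNA integrity, was 0.978 ± 0.117 and 0.966 ± 0.0659 for actin (p = 0.9), and 1.32 ± 0.0227 and 1.23 ± 0.123 for GAPDH (p = 0.3), without and with irradiation. The 5S ribosomal RNA control gave 411 ± 67.1 and 266 ± 34.0 (exact permutation test, p = 0.1, the smallest possible).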

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

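Cyclic loess normalization and its values were chosen only after the result was seen; the other alternatives were planned. The count of 383 changed probe sets (279 higher, 104 lower) was 171 (146 and 25) without an intensity trend, 223 (175 and 48) without a filter, and 202 to 279 (150 to 213 higher, 45 to 70 lower) when 1 array was left out. Fits without 1 array have less power. Over 1.5 times fewer were called without irradiated replicate 2 (202), irradiated replicate 1 (228) and unirradiated replicate 1 (232). For lower probe sets this also held without unirradiated replicate 2 (55) and unirradiated replicate 3 (63). Under the other alternatives the count stayed within 1.5 times, and the share higher, 72.8%, became 85.4% without a trend and 66.9% with median centring. Of 45 named changed genes, 26 kept their call without a trend, 33 without a filter and 32 in all 6 fits without 1 array. Among named genes without a call, 6 gained one under at least 1 alternative, Krt14 among them. The number of G2 and mitosis genes that rose was 35 without a trend and 45 to 49 without 1 array.

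The shift of G2 and mitosis genes kept its call under every alternative run, with medians from 0.61 to 0.71. With an estimated correlation 9 lists lost theirs at unchanged medians: DNA replication 0.33, damage and repair 0.18, regulators 0.082, basal markers -0.080, NRF2 -0.082, oxidative phosphorylation -0.12, ribosomal -0.13, glycolysis -0.15 and differentiation -0.17. Of these, basal, differentiation, ribosomal, oxidative phosphorylation and glycolysis lists also lost it with fry. The ribosomal median was -0.0053 with quantile and -0.0047 with cyclic loess normalization, both past no threshold. Regulators lost the call at the 60th percentile (0.072) and with averaged probe sets (0.063), and ranged from 0.067 to 0.117 without 1 array; glycolysis ranged from -0.200 to -0.085. The cause was not tested.

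The following lists and genes, all without a call, changed sign under some alternatives. TGF-beta was -0.0014 (cyclic loess), -0.0067 (quantile), -0.022 (median centring), -0.023 (no filter) and -0.047 to 0.043 without 1 array. The unfolded protein response was 4.87e-05 (cyclic loess), 0.015 (quantile) and -0.061 to -0.0022 without 1 array, called without irradiated replicate 3 (-0.035). Interferon was -0.077 (60th percentile), -0.0029 (median centring) and -0.021 to 0.078 without 1 array. Immediate-early genes were 0.0057 (no filter) and 0.0090 (averaged probe sets). The p53 list was -0.0068 (median centring) and -0.0083 to 0.031 without 1 array. Other skin cell markers ranged from -0.193 to 0.055. Cdkn1a was -0.022 (median centring), -0.0058 without unirradiated replicate 3 and -0.012 without irradiated replicate 1, with 0.037 the highest without 1 array; Ccng1 was -0.013 without unirradiated replicate 3 and -0.022 without irradiated replicate 3, with 0.122 the highest. Cholesterol synthesis kept its sign, from -0.080 to -0.012 without 1 array, and was called without unirradiated replicate 2 (-0.080). The cause was not tested. Of 12417 dim probe sets left out, limma called 0, with 625 at an unadjusted p under 0.05.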

Other observations

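The tests by quantile normalization of the lists fixed beforehand and their criteria, the comparison of G2 with replication genes, the scan of gene families and the splits for ribosome biogenesis were chosen only after the result was seen. Grouping genes by the letters that start their symbols gave 117 families. Of 23 kinesin genes (Kif), which include members of the mitotic list, 10 rose and 0 fell, with a median log2 change of 0.26 (camera adjusted p = 1.5e-09, and adjusted p = 0.486 with an estimated correlation). The 22 nucleoporin genes (Nup), of the nuclear pore, had a median of 0.22 with 1 that rose, Nup37, named after its value was seen (adjusted p = 1.4e-04, and 0.692 with an estimated correlation). The 13 keratin genes (Krt), which include members of the basal list, had a median of -0.34. Of these 2 fell, Krt15 and Krt17 (camera adjusted p = 2.0e-05 for the family, and 0.486 with an estimated correlation). The call of the family stood with quantile normalization (1.2e-04), while that of 29 large-subunit ribosomal protein genes (Rpl) did not (0.651). Lists matched in intensity were not drawn for families, so an effect of brightness stays open for the keratins.

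The rise of G2 and mitosis genes could come from an intensity-dependent difference between arrays or from 1 array. Against the first, the median was 0.70 with quantile normalization (camera adjusted p = 0.0035 with an estimated correlation), and against the second, the lowest median without 1 array was 0.61. A larger share of cells cycling in every phase stays open beside a larger share of cells in G2 or mitosis, since replication genes rose too. The mean of G2 and mitosis genes less that of replication genes was 1.07 ± 0.0277 without and 1.38 ± 0.0220 with irradiation (SD, n = 3), a difference of 0.31 seen in 3 of 3 irradiated arrays (exact permutation test p = 0.1, the smallest possible). A larger cycling share was taken to need a difference under the larger SD, which was not met, so the values argue against equal rises of both lists. The opposite criterion, a replication median below 0, was not met either (0.33), and unequal rises stay open.

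The lower values of several lists may reflect the lower signal of bright probe sets on irradiated arrays. For ribosomal protein genes, quantile normalization left a median of -0.0053 (adjusted p = 0.653), which is what this explanation needs. It stays open for basal markers (-0.059, adjusted p = 0.0026), since 16.4% of 10000 intensity-matched draws lay as low, while glycolysis kept 82.8% of its median (-0.12, adjusted p = 0.0121; 0.01% of draws), but its mean then differed by -0.12, within the SD of 0.149 among unirradiated arrays, so that whether the list changed at all stays open. Against brightness as the whole cause, the mean of oxidative phosphorylation genes still differed by -0.065 after quantile normalization, against SDs of 0.0208 and 0.0249. The list kept 51.5% of its median (-0.060, camera adjusted p = 0.0059 with the preset correlation, 0.31% of draws). The draws ignored correlation between members of a list, estimated at 0.16 here as deposited, so their share alone cannot decide the question. Differentiation markers kept 92.9% (-0.16, adjusted p = 6.7e-05), with a difference of -0.19 against SDs of 0.0631 and 0.0128; with an estimated correlation neither list passed (adjusted p = 0.383 and 0.193), and a biological change is untested.

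Myc fell, and genes of ribosome biogenesis, which MYC is known to induce, might fall with it. The list of 135 was written before its test, but it was not among the 20 lists chosen before the data were examined. Its member Wdr46 was also among the largest falls named above. Of 128 measured, 106 were below 0 as deposited, 8 fell and 0 rose; those that fell, named after their values were seen, include Wdr46 (-0.74), Pum3 (-0.66), Tma16 (-0.59) and Tsr1 (-0.46). After quantile normalization the median was -0.18 (camera adjusted p = 5.9e-14, and adjusted p = 0.162 with an estimated correlation). The size of that median was 0.183 in the real split of the arrays and at most 0.118 in the 9 others. A lower list is what the hypothesis needs, but the list did not pass with an estimated correlation. Lists matched in intensity were not drawn for these genes, and the direction of cause was not tested.

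Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave 383 changed probe sets, and the highest other gave 0 by limma, with at most 1003 at an unadjusted p under 0.05 against 2482. For lists with the preset correlation, 2 of the 10 splits gave 10 or more, and the highest other gave 11. The splits are too few for a share under 0.05. The other splits mix groups and so carry part of the real difference: the median size of G2 and mitosis genes was 0.17 to 0.26 in them and 0.69 in the real one. A part of that difference does not account for a mixed split that called 11 lists against 10 in the real one. The 9 other splits called 2 to 11 lists, so passing with the preset correlation does not by itself tie a list to irradiation. Among 57 control probe sets, limma called 0, with 3 at an unadjusted p under 0.05.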
